A study of Mus musculus with 127 samples.

How the data were processed

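Single cells of mouse marrow were captured on a microfluidic system and imaged for Ter119, and their cDNA was amplified with SMART-Seq chemistry and made into Nextera XT libraries, per the labels' protocols. Each of the 127 samples was 1 cell: 48 Flvcr-deleted, 48 wild-type and 31 EPO-treated. The values used were RPKM, read numbers scaled to transcript length and sequencing depth, deposited by the authors as 1 table with a row per RefSeq transcript and a column per cell. Reads were aligned with TopHat2 2.0.9 to mm9, per the submitters' processing notes. The counting tool, the reads that the depth refers to, the handling of reads with several matches and any filter on cells are not given in the sources used here. The table had 34898 rows and 24320 gene symbols. Of its columns, 4 belonged to no sample and were not used here.

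The columns of the EPO-treated cells differed in format from the others, so they might have been processed apart. In them 100% of the values above 0 had at most 2 decimals, and 43 of 43 RefSeq identifiers with 2 rows had equal values in both rows, against 14 of 47 in Flvcr-deleted and 5 of 51 in wild-type columns. The 2 genes 4933409K07Rik and BC002163 were at 0 in every EPO-treated cell while their mean log2 level was at least 1 in both other groups. Contrasts with EPO-treated cells therefore mix the group with any such difference.

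A gene was 1 symbol; where a symbol had several rows, as 5556 had, the row with the highest mean RPKM was used. Values were taken as log2(RPKM + 1), on which scale the change of a gene near 0 is understated. The 2540 genes with a mean of at least 1 over all cells were kept for lists and rankings. A gene counted as detected in a cell at an RPKM of at least 1. Shares of cells have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Read depth was estimated as the number of reads that makes the smallest step between a column's length-corrected values 1 read, with transcript lengths from the mouse annotation GENCODE vM21 matched by RefSeq identifier; 97.8% of rows had a length. That annotation is of another build than mm9, so only its lengths were used, and the estimate is approximate. The share of reads in listed transcripts was estimated per cell as the sum of RPKM times transcript length, which the unknown read total and the lengths of another build make rough, and the share of summed RPKM in globin genes was taken per cell.

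Because the labels named no animal, each group was 1 sample, and no p-value, standard error or count of changed genes was made from cells. The difference between groups was taken within each class letter and averaged over the 4 letters with equal weight, since the groups held the letters in unlike shares. It was taken for Flvcr-deleted minus wild-type, EPO-treated minus wild-type and Flvcr-deleted minus EPO-treated cells. Class D minus class A was taken within each group, and suffix d minus suffix a within class A of Flvcr-deleted cells. Spearman's rho with the Ter119 value was taken within chips.

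Before the data were examined, 31 gene lists were fixed: 23 of pathways, complexes and gene programs and 8 of markers of other cell types, of which 3 members were not in the table. The 21 lists with at least 3 kept members were described by the median difference and its percentile among 10000 random lists of the same size, drawn from 20 bins of mean level. Where a list filled a large part of a bin, the remaining genes were drawn with replacement, which leaves a thin reference. A list was called apart in the outer 2.5% of random lists on either side. A member counted as higher or lower where its difference had a size of at least 1 and the same sign in all 4 letters. The share of all kept genes that met this rule is not given here. Counts of lower members therefore include any shift of the median gene, and only the percentile sets a list against other genes. Lists with fewer kept members are given as single genes or as shares of cells with at least 3 detected markers. The GATA1-activated list holds globin and heme synthesis genes, so these lists are not independent.

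The rule for named genes was fixed at the same time. For each group contrast it took the 12 largest differences in each direction among kept genes with a size of at least 1 and the same sign in all 4 letters. For class and suffix contrasts it took the 8 largest in each direction with a size of at least 1. It added Flvcr1, Flvcr2, Hmox1, Alas2, Tfrc, Gata1, Klf1, Cish and Kit in each contrast, a further gene that is not reported here, and the 4 members of each list with the largest absolute difference. The text names part of what the rule gave. Fam132b and BC002163 are named for shares or values singled out after they were seen.

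The scripts were tested on values simulated with the cell numbers of the Flvcr-deleted and wild-type comparison. Both simulated groups were drawn with replacement from wild-type cells of the same letter, so they lacked the real difference in depth. Among 3518 simulated genes, 50 genes made 3 log2 units lower had a median difference of -1.24, 98% with the right sign and 56% past the size rule. Of 50 genes made 2 units lower 30% passed, of 50 made 2 units higher 46%, and of 50 made 3 units higher 46%. Of 3318 unchanged genes 1.21% passed, a share that does not cover passes brought by unlike depth. Lists were tested on the real differences of that comparison: of 200 random lists of 30 genes, 7% were called apart with no shift and 100% with a shift of 1.

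Alternatives were other pseudocounts (0.1 and 10), no filter or a mean of at least 3, unweighted means over cells, scaling to 1 sum with and without globins, quantile normalization, the sum of rows per symbol and a log2 ratio of mean RPKM. Others left out cells with few detected genes, a suffix, the smaller EPO chip or each class letter in turn. Added after the data were seen were random lists matched on transcript length too, cells with 800 to 3000 detected genes, member counts without class A, and class B to D cells with 1000 to 2000 detected genes, also with each of these classes left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Doublets were not called, since no tool for it was used here.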

Results

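The data were transcript levels of 127 single marrow cells of C57BL/6J mice, each labelled as an erythroblast. The cells formed 3 groups: 48 Flvcr-deleted cells, 48 wild-type cells and 31 cells of wild-type mice treated with erythropoietin (EPO), the hormone that drives red cell production. Each cell carried a class letter from A to D, which within a capture chip followed its fluorescence for Ter119, a surface antigen of maturing red cells, except that 1 EPO-treated class D cell (0.358) lay below 1 class C cell (0.366). Class A held 18 Flvcr-deleted, 6 wild-type and 7 EPO-treated cells, class B held 16, 10 and 11, class C held 9, 19 and 9, and class D held 5, 13 and 4. No animal was named for any cell, so each group counted as 1 sample, no p-value could be given, and no difference has a replicate check. Differences below are class-weighted differences of mean log2(RPKM + 1), every SD is over cells and describes those cells alone, and chip and group cannot be told apart.

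The groups differed in depth. The median number of genes detected per cell (RPKM of at least 1) was 1069 in Flvcr-deleted cells (169 to 3452), 2422 in wild-type cells (1151 to 4047) and 1441 in EPO-treated cells (638 to 3982). Sequenced reads, estimated from the smallest step between values, had a median of 2.68 M in Flvcr-deleted cells (0.0576 to 4.88 M) and 4.00 M in wild-type cells (2.01 to 5.35 M). Without the suffix d cells the Flvcr-deleted median was 3.28 M. In classes B, C and D median reads were 3.01, 3.53 and 3.88 M in Flvcr-deleted and 3.83, 4.06 and 4.13 M in wild-type cells. Median detected genes in these classes were 1235, 1179 and 1214 against 3033.5, 2152 and 1891, so they differed more than the reads did. Rounding hid that step in the EPO-treated columns, so their read depth is unknown. Globin transcripts took a median share of 54.2% of the summed values per cell in Flvcr-deleted, 46.1% in wild-type and 38.5% in EPO-treated cells.

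**Figure D1:**
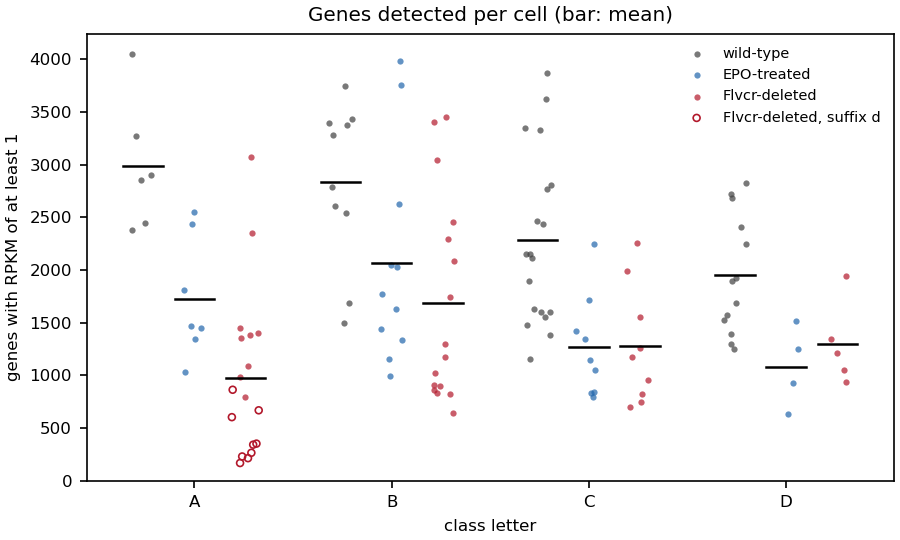
Genes with an RPKM of at least 1 (y axis, number of genes) in each of the 127 cells by class letter (x axis), with 1 point per cell, colours for the 3 groups, open circles for the Flvcr-deleted cells with suffix d and a bar at the mean. The suffix d cells lie between 169 and 864 genes, below every wild-type cell, the lowest of which has 1151.

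Class A was not alike between the groups. In wild-type cells of class A the globin share did not exceed 0.193%, in EPO-treated cells its median was 1.25%, and in Flvcr-deleted cells it was 17.0%. At least 3 granulocyte and monocyte markers were detected in 5 of 6 wild-type class A cells (83.3%, exact 95% interval 35.9% to 99.6%), in 4 of 7 EPO-treated ones (57.1%, 18.4% to 90.1%) and in 1 of 18 Flvcr-deleted ones (5.56%, 0.14% to 27.3%). Of those 18 cells 9 had suffix d, with a median of 343 detected genes against 2878 in wild-type class A, so markers could be missed there. The same 9 cells count in the shares of Flvcr-deleted cells given below. Values over classes B to D alone are therefore given beside those over all 4 classes for many of the lists. These classes also held cells low in globin. Flvcr-deleted class B cells 7, 13, 16 and 40 had Alas2 at 0 and Hbb-b1 at log2 levels of 10.99, 10.11, 8.26 and 8.31. The lowest Hbb-b1 level in wild-type and EPO-treated cells of classes B to D was 12.83. These cells lower the Flvcr-deleted means of Alas2 and Hbb-b1 over classes B to D. Each had more than 2000 detected genes, so the range of 1000 to 2000 leaves them out.

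The comparison of Flvcr-deleted with wild-type cells addressed how loss of Flvcr, a cell surface transporter known for heme export, goes with the levels of erythroid transcripts at the same Ter119 class. Flvcr1, listed under its older symbol Mfsd7b (NM_001081259), was detected in 0 of 48 Flvcr-deleted cells, which allows a share of up to 7.40% (exact 95% interval). It was detected in 1 of 48 wild-type cells (2.08%, 0.0527% to 11.1%), a class A cell, and in 0 of 31 EPO-treated cells (up to 11.2%). The transcript was too rarely detected to tell the genotypes apart at this depth. Its relative Flvcr2 (listed as Mfsd7c, NM_145447) was detected in 1 wild-type cell, of class B.

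Gata1 (NM_008089), the transcription factor that directs erythroid genes, was lower in Flvcr-deleted cells by a difference of -4.10. It was detected in 17 of 48 Flvcr-deleted cells (35.4%, exact 95% interval 22.2% to 50.5%) against 43 of 48 wild-type cells (89.6%, 77.3% to 96.5%). In class B its mean log2 level was 2.06 ± 2.86 (SD, n = 16 cells) in Flvcr-deleted and 6.88 ± 1.21 (n = 10) in wild-type cells, and in class D 1.23 ± 1.27 (n = 5) against 6.91 ± 1.53 (n = 13). The median of the 2540 genes compared differed by -1.21, so relative to it Gata1 lay at -2.89. Its partner factors Gfi1b (NM_008114) and Klf1 (NM_010635) differed by -2.97 and -2.22. Of the 12 erythroid transcription factors compared, 4 were lower and 0 higher (7 and 0 over classes B to D), and their median of -1.36 lay at percentile 61.9 among 10000 random lists of matched level.

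Heme synthesis genes were lower in Flvcr-deleted cells of classes B to D. Ppox (NM_008911) differed by -5.33 over these classes, Slc25a38 (NM_144793), a mitochondrial carrier needed for heme synthesis, by -3.70, and Fech (NM_007998), which inserts iron to make heme, by -3.55. Alas2 (NM_001102446), the erythroid enzyme of the first step, differed by -2.23, from 10.99 ± 0.85 in wild-type class D (n = 13) to 8.66 ± 1.80 in Flvcr-deleted class D (n = 5). Over classes B to D, 11 of 11 members were lower, with a median of -2.83 at percentile 0.18. The median of the 2540 genes compared differed by -1.08 over these classes, so counts of lower members here and below include that shift. The Flvcr-deleted class B cells with Alas2 at 0 count in these values. In class B to D cells with 1000 to 2000 detected genes, which leave them out, Alas2 differed by -2.63. The heme synthesis list lay at percentile 0.05 there. With class A included, 5 of 11 were lower and 0 higher, and the median of -2.27 lay at percentile 3.13.

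GATA1-activated genes as a list lay low when class A was left out or when every cell was weighted alike (percentile 0.03, median -2.46), but not over the 4 classes weighted alike. Weighting every cell alike mixes level with class make-up, as class A held 18 of 48 Flvcr-deleted and 6 of 48 wild-type cells. Over classes B to D, 19 of 30 members were lower and 0 higher, with a median of -1.97 at percentile 0.22; examples are Gata1 at -4.99 and Epb4.2 (NM_013513), a red cell membrane protein, at -3.71. Over all 4 classes 6 of 30 were lower and 2 higher, and the median of -1.10 lay at percentile 66.9. Globins went the other way: Hbb-b1 (NM_001278161) differed by 2.81 and Hba-a1 (NM_008218) by 1.84, 4 of 9 members were higher and 0 lower, and the median of 1.71 lay at percentile 100. Most of that came from class A, where Hbb-b1 differed by 8.75; over classes B to D it differed by 0.83, and the list median of 0.82 lay at percentile 97.3. With every cell weighted alike in place of the classes, Hbb-b1 differed by -0.032. Adult beta-globin and alpha-globin copies share reads, so their single values are uncertain. Whether reads of adult globins were also counted for the embryonic ones is not known. Of the 25 red cell membrane and skeleton genes 8 were lower, with a median of -1.27 at percentile 40.8; over classes B to D 19 were lower. That list lay low and apart with a pseudocount of 10 (2.26), with every cell weighted alike (1.56) and with the ratio of mean RPKM (1.83).

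Cish (NM_009895), a feedback gene of EPO receptor and STAT5 signalling, was higher in Flvcr-deleted cells by 2.57. It was detected in 20 of 48 Flvcr-deleted cells (41.7%, exact 95% interval 27.6% to 56.8%) and 4 of 48 wild-type cells (8.33%, 2.32% to 20.0%). In class D it was detected in 5 of 5 Flvcr-deleted cells and 0 of 13 wild-type cells. Pim1 (NM_008842), another STAT5 target, differed by 1.37, and Ccnd3 (NM_007632), a cyclin, by -2.89. Of the 5 members of the EPO receptor and STAT5 list compared, 1 was higher and 2 lower, with a median of -1.16 at percentile 48.4. Nupr1 (NM_019738), a stress-response gene, differed by 2.17 and was detected in 17 of 48 Flvcr-deleted and 0 of 48 wild-type cells. The metallothioneins Mt2 (NM_008630) and Mt1 (NM_013602) were higher by 1.54 and 1.42. Hmox1 (NM_010442), the heme-degrading enzyme, was detected in 2 of 48 Flvcr-deleted and 0 of 48 wild-type cells and differed by 0.46.

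**Figure D2:**
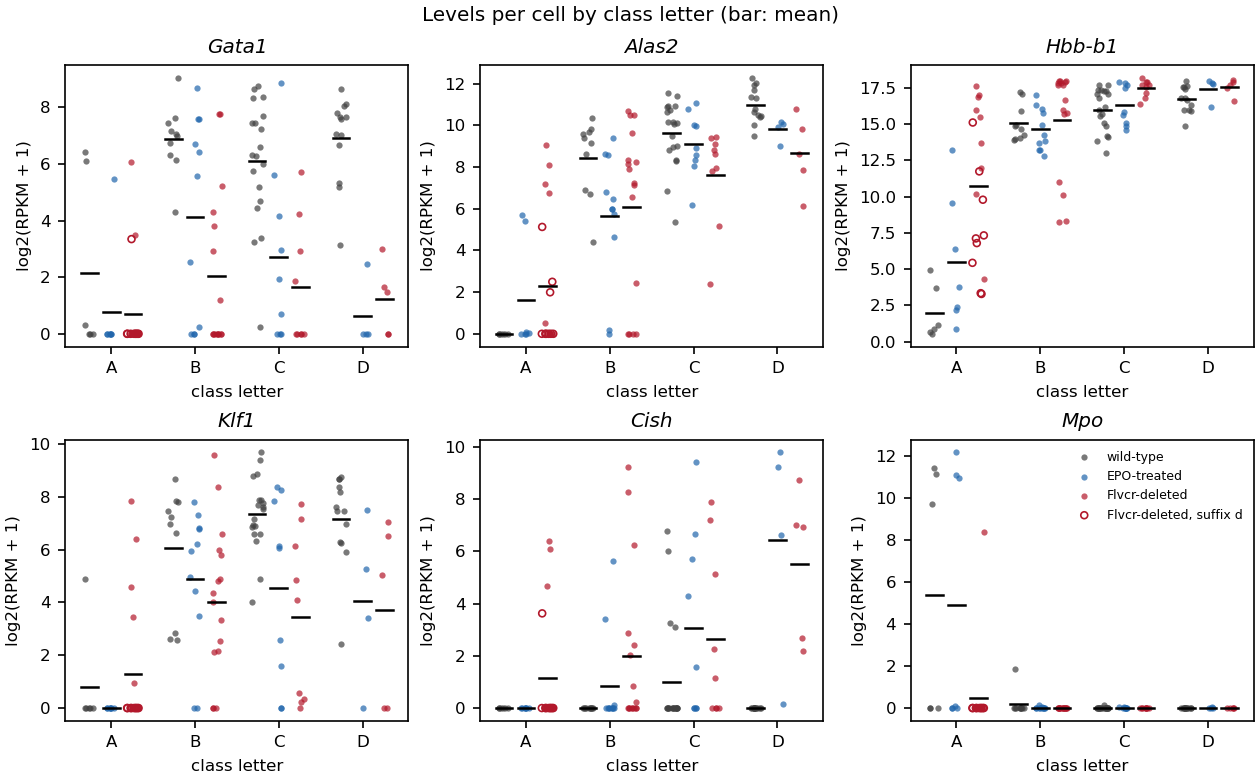
Level of 6 genes in each cell (y axis, log2(RPKM + 1)) by class letter (x axis), with colours for the 3 groups, open circles for the suffix d cells and bars at the means. In class D the mean Gata1 level is 1.23 in Flvcr-deleted, 6.91 in wild-type and 0.61 in EPO-treated cells, and that of Cish is 5.51, 0 and 6.45.

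Cell division genes were lower in Flvcr-deleted cells over all 4 classes, but for DNA replication this depended on genes detected per cell. In the DNA replication list 40 of 46 members were lower and 0 higher, with a median of -2.01 at percentile 0.00, among them Mcm3 (NM_008563) at -4.09, Slbp (NM_001289724) at -4.05 and Rrm1 (NM_009103) at -3.70; in class B to D cells with 1000 to 2000 detected genes it lay on the other side, at 98.98 with a median of 0.46. In the mitosis and spindle list 29 of 53 were lower and 0 higher (44 and 0 over classes B to D), with a median of -1.84 at percentile 0.59 (3.36 with every cell scaled to 1 sum), among them Cdk1 (NM_007659) at -3.74 and Cdca8 (NM_026560) at -3.63. Proteasome genes were lower in 22 of 30 cases, with a median of -2.06 at percentile 3.69, such as Psmc4 (NM_011874) at -3.26. That list lay low and apart under 4 alternatives, among them lists matched on transcript length (2.11) and 1 sum without globins (1.31), but on the other side, at 96.7 with a median of 0.24, in class B to D cells with 1000 to 2000 detected genes.

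Ribosomal protein and oxidative phosphorylation genes stood above random lists of their level. The ribosomal protein median was 0.31 at percentile 100, with 0 of 82 members higher and 4 lower over all 4 classes and 53 higher and 2 lower over classes B to D. Rpl39 (NM_026055) differed by 1.39 and Rpl4 (NM_024212) by -2.42. The sign of that median depended on scaling: it was -0.52 with every cell scaled to 1 sum and -0.04 with the globins left out of the sum, at percentiles of 100 in both. The oxidative phosphorylation median of -0.87 lay above that of the median gene, at percentile 99.9, with 18 of 65 members lower and 0 higher (18 and 5 over classes B to D), such as Atp5b (NM_016774) at -3.26; it lay at 86.2 when the random lists were matched on transcript length too.

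Of the genes past the filter with the same sign in all 4 letters, ranked by size, the highest in Flvcr-deleted cells after the beta-globins and Cish were Cox6b2 (NM_183406) at 1.85 and the embryonic globin Hbb-bh1 (NM_008219) at 1.71. The lowest were the RNA-binding protein gene Hnrnpk (NM_001301345) at -5.88, the class I antigen gene H2-L (NM_001267808) at -5.35, Tuba1b (NM_011654) at -5.10, Hnrnpf (NM_133834) at -5.01 and Dazap2 (NM_011873) at -4.96. Hnrnpk was detected in 17 of 48 Flvcr-deleted and 48 of 48 wild-type cells. Ppp1r15a (NM_008654), a stress-response gene, differed by -4.53, and Eif5a (NM_001166595) by -4.54. Tuba1b shares reads with the near-identical Tuba1a and Tuba1c.

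The other lists did not stand apart from random lists over all 4 classes. Their percentiles were 65.3 for iron uptake and iron-sulfur assembly, 71.9 for the heme and oxidative stress response, 73.6 for the integrated stress and unfolded protein response, 74.3 for p53 targets and 46.5 for organelle clearance and autophagy (0.72 in class B to D cells with 1000 to 2000 detected genes). They were 29.9 for ribosome biogenesis, 14.9 for glycolysis, 64.3 for apoptosis regulators (98.8 without class A), 16.5 for immediate early and heat shock genes and 48.4 for the interferon response. With no filter on low values glycolysis lay at 0.27, the interferon response at 0.05 and p53 targets at 97.7. The heme transporter list had 2 members to compare, Slc48a1 (NM_026353) at -1.70 and Abcg2 (NM_011920) at 0.07, and the GATA1-repressed list had 1, Ikzf1 (NM_001301866) at -2.34. Tfrc (NM_011638), the transferrin receptor, differed by -1.16. Its difference was -1.78 with every cell scaled to 1 sum, -0.34 after quantile normalization and -0.43 in class B to D cells with 1000 to 2000 detected genes. Kit (NM_021099), a progenitor receptor, was detected in 0 of 48 Flvcr-deleted and 2 of 48 wild-type cells and differed by -0.29.

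Flvcr-deleted and wild-type cells differed in genes detected per cell, and among class B to D cells with 1000 to 2000 detected genes (12 and 18 cells, with 4, 4 and 4 against 2, 8 and 8 in classes B, C and D), a range set after the data were seen, Gata1 differed by -4.36, Cish by 3.22 and Alas2 by -2.63, with heme synthesis at percentile 0.05 and GATA1-activated genes at 0.00. In that range the median gene differed by -0.09, the DNA replication list turned to the other side at percentile 98.98 (78.6 without class C and 73.1 without class D), globins lay at 44.5, Hbb-bh1 differed by -0.024, H2-L differed by -1.53, red cell membrane genes lay at 0.00 with a median of -2.02, and the ribosomal protein and oxidative phosphorylation medians were 3.57 and 1.43, both at percentile 100. With each of these classes left out in turn the lists of heme synthesis, GATA1-activated, red cell membrane, ribosomal protein and oxidative phosphorylation genes stood apart on the side given. The range kept wild-type class B cells with globin shares of 61.3% and 64.3%, against a median of 33.0% in that class. These cells were therefore not typical of their class.

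**Figure D3:**
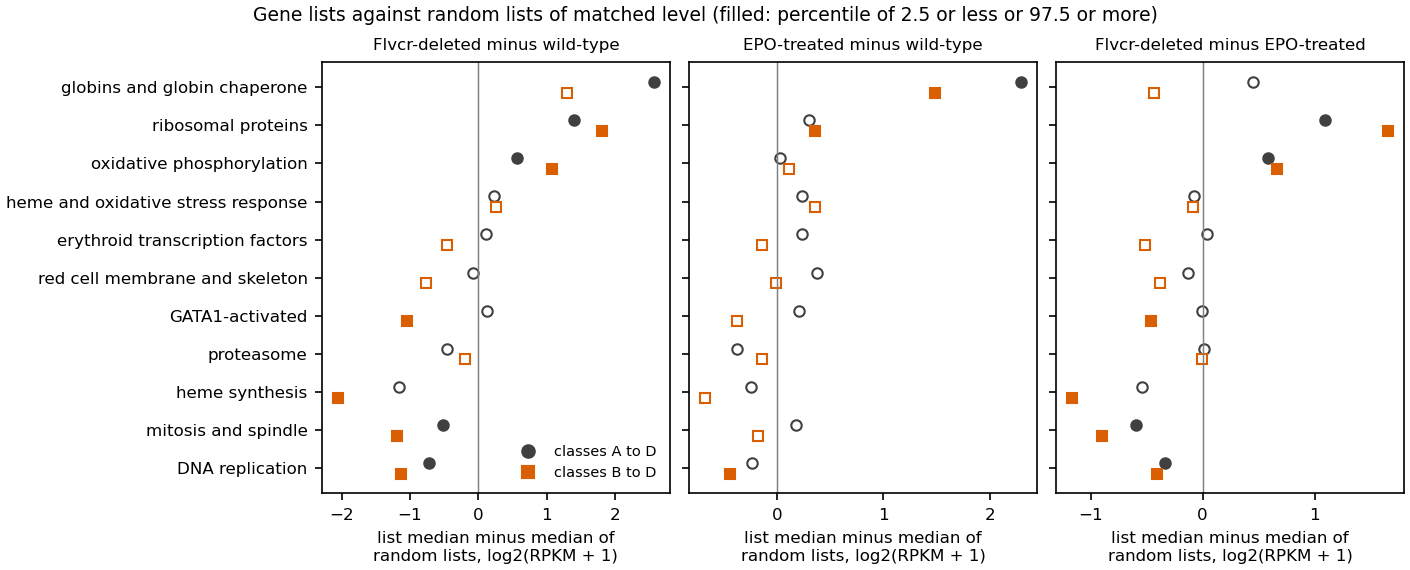
Median of each gene list minus that of random lists of matched level (x axis, log2(RPKM + 1) units) for 11 lists and the 3 group contrasts, over classes A to D (circles) and B to D (squares), filled where the list lies in the outer 2.5% of random lists on either side. Over classes B to D against wild-type cells, heme synthesis (percentile 0.18) and GATA1-activated genes (0.22) of Flvcr-deleted cells lie to the left of 0 and ribosomal proteins (100) to the right.

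The comparison of EPO-treated with wild-type cells addressed how stimulated erythropoiesis differs from that at rest. A class letter covered unlike normalized Ter119 values in these groups. Medians in classes A to D were 0.018, 0.099, 0.281 and 0.556 in EPO-treated and 0.145, 0.452, 0.643 and 0.823 in wild-type cells. The EPO-treated medians pool both chips of that group. The 4 cells of the smaller chip, 1 of them of class C, lay at 0.00263 or less. Every cell of the other chip, class A included, lay at 0.00605 or more. The values are therefore not on 1 scale across these chips, and whether they compare across the others was not tested. Cells of the same letter may differ in stage, but these values cannot show it. Flvcr1 (Mfsd7b) was detected in 0 of 31 EPO-treated and 1 of 48 wild-type cells. Gata1 was lower by -3.46, detected in 14 of 31 EPO-treated cells (45.2%, exact 95% interval 27.3% to 63.97%), with a mean of 4.12 ± 3.56 in class B (n = 11) and 0.61 ± 1.23 in class D (n = 4). Cish differed by 2.34 and was detected in 10 of 31 cells (32.3%, 16.7% to 51.4%), 0 of 7 in class A and 3 of 4 in class D. Fam132b (NM_173395), the erythroblast hormone gene also called Erfe, was detected in 11 of 31 EPO-treated cells (35.5%, 19.2% to 54.6%) and 3 of 48 wild-type cells (6.25%, 1.31% to 17.2%), and in 12 of 48 Flvcr-deleted cells (25.0%, 13.6% to 39.6%). The embryonic beta-like globins were higher, Hbb-bh1 by 1.85 and Hbb-y (NM_008221) by 2.92, although Hbb-bh1 differed by 0.70 among class B to D cells with 1000 to 2000 detected genes. Reads of adult globins counted for them cannot be excluded, as the handling of reads with several matches is not given.

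The median gene was lower in EPO-treated cells by a difference of -1.02, and 3 of 21 lists stood apart. Globins lay at percentile 100 with a median of 0.96, although 1 of 9 members was higher by the rule and 0 lower. Organelle clearance and autophagy genes lay at percentile 1.67 with a median of -1.95, 5 of 9 lower, such as Map1lc3b (NM_026160) at -2.69 and Gabarap (NM_019749) at -2.58, both autophagosome proteins; that call was lost under 14 alternatives, among them both other pseudocounts, both scalings to 1 sum, quantile normalization, lists matched on transcript length and leaving out the 4 cells of the smaller chip (percentile 16.5). Glycolysis genes lay at percentile 0.55 with a median of -1.69, 5 of 10 lower, such as Gapdh (NM_001289726) at -2.26; over classes B to D that list lay at 58.9. The DNA replication list had 24 of 46 members lower, such as Mcm7 (NM_008568) at -3.54, with a median of -1.42 at percentile 6.10, and at 0.53 over classes B to D, but at 99.1 with a median of 0.40 in class B to D cells with 1000 to 2000 detected genes. Mitosis and spindle genes lay at 84.1, with 19 of 53 lower, and at 13.2 with 30 lower over classes B to D.

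Heme synthesis genes were lower in 5 of 11 cases in EPO-treated cells, with a median of -1.68 at percentile 26.8, and in 8 of 11 cases over classes B to D, at percentile 3.52. Alas2 differed by -0.72, by -1.49 over classes B to D, and by -2.14 in class B to D cells with 1000 to 2000 detected genes. GATA1-activated genes were lower in 10 of 30 cases, with a median of -1.13 at percentile 79.9, and in 18 of 30 cases over classes B to D, at 5.65. Klf1 differed by -1.97. Tfrc differed by -0.46, and by 0.14 after quantile normalization. Ribosomal proteins lay at 93.3 with a median of -1.20, and stood apart on the high side under 8 alternatives, at 98.7 without class A, 99.95 with lists matched on transcript length, 99.8 in cells with 800 to 3000 detected genes and 100 with a median of 1.34 in class B to D cells with 1000 to 2000. Oxidative phosphorylation lay at 56.3, and in the latter cells at 100 with a median of 0.66. Over all 4 classes red cell membrane genes lay at 94.2 with 4 of 25 lower (47.3 with 14 lower over classes B to D), erythroid transcription factors at 78.5 with 3 of 12 lower (33.2 with 6 lower) and EPO receptor and STAT5 targets at 81.7. Pim1 was detected in 14 of 31 EPO-treated and 12 of 48 wild-type cells.

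Besides Hbb-bh1, 5 genes met the rule for higher genes in EPO-treated cells: Hnrnpl (NM_177301) at 1.37, Osbpl8 (NM_001003717) at 1.27, Plek2 (NM_013738) at 1.25, 1810037I17Rik (NM_024461) at 1.10 and the DNA ligase gene Lig3 (NM_001291246) at 1.05. The lowest of those with the same sign in all 4 letters were Dazap2 at -4.72, H2-L at -4.65, Eif5a at -4.47, Hnrnpk at -4.27 and Ap1b1 (NM_007454) at -3.94. Hmox1 was detected in 0 of 31 EPO-treated and 0 of 48 wild-type cells, and Kit in 2 of 31 and 2 of 48. Among class B to D cells with 1000 to 2000 detected genes (12 EPO-treated cells, with 5, 5 and 2 in classes B, C and D, and 18 wild-type cells), Gata1 differed by -4.44, Cish by 1.52, Klf1 by -0.66, H2-L by -0.95, Ap1b1 by -1.33 and Mcm7 by -1.91. In these cells heme synthesis lay at 1.49, GATA1-activated genes at 0.04, red cell membrane genes at 0.10, mitosis at 0.36, DNA replication at 99.1, globins at 44.6, glycolysis at 84.0, the interferon response at 1.10, ribosome biogenesis at 99.7, EPO receptor and STAT5 targets at 98.6 and immediate early and heat shock genes at 99.4. With 1 of these classes left out the calls among them were lost, except for red cell membrane genes: without class B, which held 2 wild-type cells, heme synthesis lay at 5.78, GATA1-activated genes at 3.35, mitosis at 19.1, DNA replication at 86.7, ribosome biogenesis at 96.1, EPO receptor and STAT5 targets at 69.9 and immediate early genes at 85.9, Klf1 differed by -1.85, and without class C the interferon response lay at 6.41. The Klf1 difference all but vanished without class C.

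Flvcr-deleted cells were also set against EPO-treated cells, that is against stimulated erythropoiesis. Median normalized Ter119 values of Flvcr-deleted classes A to D were 0.150, 0.381, 0.608 and 0.849, above those of EPO-treated cells. Here too, cells of the same letter may differ in stage, but values that may not compare across chips cannot show it. Flvcr1 (Mfsd7b) was detected in 0 of 48 and 0 of 31 cells. The median gene differed by -0.26. Gata1 differed by -0.64, Klf1 by -0.25, Alas2 by -0.38, Cish by 0.24, Tfrc by -0.70 and Kit by -0.33; among class B to D cells with 1000 to 2000 detected genes Gata1 differed by 0.08 (-0.02 without class C), Klf1 by -1.05 (-0.35 without class D), Tfrc by 0.32 (-0.48 without class B), Cish by 1.70, Ppox by -1.69, Ptma by -1.24 and Mapre1 by -1.46. The heme synthesis enzyme Ppox was lower in Flvcr-deleted cells by -2.81, detected in 16 of 48 Flvcr-deleted cells (33.3%, exact 95% interval 20.4% to 48.4%) and 20 of 31 EPO-treated cells (64.5%, 45.4% to 80.8%). The heme synthesis median was -0.59 at percentile 6.04 and, over classes B to D, -0.94 at percentile 0.24.

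Ribosomal protein genes were higher in Flvcr-deleted than in EPO-treated cells, 12 of 82 by the rule and 53 of 82 over classes B to D, with 0 lower in both, and their median of 1.49 lay at percentile 100. Rpl29 (NM_009082) differed by 3.24, Rpl35 (NM_025592) by 3.23 and Rpl23a (NM_207523) by 2.80. Class D carried much of it: Rpl29 had a mean of 8.52 ± 0.46 (n = 5) in Flvcr-deleted and 0.95 ± 1.90 (n = 4) in EPO-treated class D cells, and without class D the list lay at percentile 86.0. Oxidative phosphorylation genes had a median of 0.40 at percentile 100, 4 of 65 higher, such as Atp5l (NM_013795) at 2.70, and 3 lower, such as Atp5b at -2.30 (14 higher and 4 lower over classes B to D); their median was -0.15 with every cell scaled to 1 sum, and they lay at 94.3 with random lists matched on transcript length; in the range of 1000 to 2000 detected genes they lay at 99.9, and at 85.4 without class D.

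Mitosis and spindle genes were lower in Flvcr-deleted than in EPO-treated cells in 14 of 53 cases with 0 higher, and their median of -0.85 lay at percentile 0.00, with Cdca8 at -2.47 and Hmmr (NM_013552) at -2.11. DNA replication genes were lower in 2 of 46 cases, with a median of -0.63 at percentile 0.12; without class B they lay at 63.2, and in the range of 1000 to 2000 detected genes at 13.7 (0.00 without class D, which held 2 EPO-treated cells). GATA1-activated genes lay at 49.2 over all classes, at 1.12 over classes B to D and at 98.2 without class D, so these cells give no steady order for that list. Globins lay at 82.3 with 2 of 9 higher (18.8 with 0 higher over classes B to D) and erythroid transcription factors at 55.8 with 0 of 12 lower (3.11 with 4 lower). Other genes lower in Flvcr-deleted cells were Dek (NM_025900) at -2.61, Ptma (NM_008972) at -2.56 and Mapre1 (NM_007896), a microtubule end-binding protein gene, at -2.46, and others higher were Sepw1 (NM_009156) at 2.44 and Gabarap at 2.25. BC002163 (NR_002445) stood 2.76 above the median gene, but it was listed at 0 in every EPO-treated cell, and the EPO-treated columns differed from the others in number format.

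The comparison of class D with class A within a group set cells of high Ter119 against cells of low Ter119 captured together. Flvcr1 was detected in 0 class D cells of any group. Alas2 was higher in class D by 6.37 in Flvcr-deleted, 10.99 in wild-type and 8.20 in EPO-treated cells. Gata1 differed by 0.51, 4.78 and -0.17, Klf1 by 2.42, 6.34 and 4.05, and Tfrc by 4.98, 3.77 and 6.01. Cish differed by 4.36 in Flvcr-deleted and 6.45 in EPO-treated cells and was 0 in both classes of wild-type cells. Kit differed by -0.05, -1.27 and -1.45. Whether these within-group differences differ between the groups was not tested.

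Globins had medians of 4.95, 7.51 and 8.92 in Flvcr-deleted, wild-type and EPO-treated cells, each at percentile 100. GATA1-activated genes were higher in class D in 21, 29 and 28 of 30 cases, with medians of 2.47, 5.28 and 3.87, each at percentile 100. Heme synthesis genes had medians of 2.20, 5.33 and 3.39, at percentiles 96.6, 99.99 and 99.99. Mitosis and spindle genes lay at percentile 100 in each group, with medians of 1.70, 2.36 and 1.89. Ribosomal proteins had medians of 1.90 in Flvcr-deleted and -2.59 in wild-type cells and were low against lists of matched level in each group (percentiles 0.01, 0.00 and 0.00), as were ribosome biogenesis genes (0.00, 0.00 and 0.08). In Flvcr-deleted cells the ribosomal proteins lost that call with a pseudocount of 0.1 (20.4) and with every cell scaled to 1 sum without globins (37.4). EPO receptor and STAT5 targets lay at 98.8 (96.2 with a pseudocount of 10), 73.5 and 99.98. The median gene differed by 0.39, -0.43 and -0.57. Class A of Flvcr-deleted cells held 9 suffix d cells, in which every ribosomal protein gene was lower than in suffix a cells, as given below. Including them raises the Flvcr-deleted differences of these genes, so their median of 1.90 is not like that of wild-type cells. Without suffix d the median gene of Flvcr-deleted cells differed by -0.34.

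Of the genes past the filter, those furthest up in class D were the adult globins in wild-type cells (Hbb-b1 14.75, Hba-a1 12.43) and in EPO-treated cells (Hbb-b1 11.94, Hba-a1 10.08). In Flvcr-deleted cells they were Hemgn (NM_053149), an erythroid nuclear protein gene, at 7.70 and the heme synthesis gene Urod (NM_009478) at 7.65. Lowest in class D were Crip1 (NM_007763) at -9.06 and Tagln2 (NM_178598) at -8.16 in wild-type, Rps18 (NM_011296) at -9.44 and Hspa8 (NM_031165) at -7.97 in EPO-treated, and Ptma at -3.19 and Gng5 (NM_010318) at -2.61 in Flvcr-deleted cells. Over the cells of 1 chip each, Spearman's rho with the Ter119 value was 0.56 for Alas2 in Flvcr-deleted cells (n = 48), 0.69 in wild-type cells (n = 48) and 0.85 in EPO-treated cells (n = 27), and for Gata1 it was 0.27, 0.31 and 0.08. For Hbb-b1 it was 0.66, 0.61 and 0.82. Cells within a chip are not independent samples, so these values describe the chips and carry no p-value; without the suffix d cells the value for Alas2 in Flvcr-deleted cells was 0.38 (n = 39). Because class A of wild-type and EPO-treated cells was rich in granulocyte and monocyte markers, the contrasts there are not of early with late erythroid cells alone.

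The labels split class A of Flvcr-deleted cells into 9 cells with suffix a and 9 with suffix d, with no stated meaning. Flvcr1 was detected in 0 of the 18. Suffix d cells had a median of 343 detected genes against 1381, and 0.222 M estimated reads against 1.57 M. The share of reads in listed transcripts was estimated at a median of 4.75% against 58.3% in suffix a cells; the estimate is rough, as it came to more than 100% in 4 other cells (up to 104%). Ribosomal protein genes were lower in suffix d in 82 of 82 cases, with a median of -7.49 at percentile 0.00, such as Rps28 (NM_016844) at -11.27, and oxidative phosphorylation genes in 62 of 65 cases, with a median of -4.62 at 0.00. Ribosome biogenesis genes lay at 98.7 with a median of -1.30, and at 94.6 with every cell scaled to 1 sum without globins. Gpx1 (NM_008160) differed by -10.05, Tfrc by -4.06, Klf1 by -2.58, Alas2 by -2.44, Cish by -1.51, Gata1 by -0.69 and Kit by -0.10. The few genes higher in suffix d cells included Luc7l3 (NM_026313) at 2.96 and Rbm25 (NM_027349) at 2.84, both coding for proteins of RNA splicing. The median gene differed by -1.38.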

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

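The tests split by list, the range of 1000 to 2000 detected genes (also for globins), the share of reads in transcripts and the tests on class A markers were chosen only after the result was seen. The globin share of 1 EPO-treated cell of class A was 25.5%, far from the other 6 cells, which lay between 0.0204% and 2.81%. Of 18 sets of cells tested for such a value this was the 1 found. Chance gives about 1 in every 20 sets where values spread normally, so 1 among 18 may be chance.

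In Flvcr-deleted cells the DNA replication and mitosis lists lay low and the ribosomal protein and oxidative phosphorylation lists high against both other groups, which makes 8 pairs of list and contrast. For globin transcripts taking a larger share of the values, rescaling without globins left 8 of 8 pairs apart but decides nothing, as 1 factor per cell moves nearly all genes alike (distances from random lists moved by at most 23.1%) and restores no undetected gene. Matching on transcript length left 6 of 8, that is 6 of 6 for replication, mitosis and ribosomal proteins, which argues against length there, and 0 of 2 for oxidative phosphorylation (86.2 and 94.3), where transcript length bias stays open. For fewer detected genes per cell, the range of 800 to 3000 detected genes left 8 of 8 pairs, but decides nothing against that cause because medians still differed (1237, 2110 and 1441 genes in Flvcr-deleted, wild-type and EPO-treated cells). The range of 1000 to 2000 without class A (medians 1278, 1566 and 1385) left 6 of 8. These were 4 of 4 for mitosis and ribosomal proteins, also with class B, C or D left out. With the median gene at -0.09 against wild-type cells in that range, this argues against low detection as their only cause there. It does not decide for all cells, as the range kept wild-type cells rich in globin. Those of class B had shares of 61.3% and 64.3%, against a median of 33.0% in the whole class. Without class B the wild-type mean in the range was 61.5%, against medians of 52.5% and 60.4% in the whole classes C and D. As medians of detected genes still differed, a part played by low detection stays open. The other pairs were 2 of 2 for oxidative phosphorylation, where low detection stays open as 1 call was lost without class D (85.4), and 0 of 2 for DNA replication (98.98 and 13.7, the latter 0.00 without class D), which may come from low detection. In that range the mean globin share was 60.1% in Flvcr-deleted, 61.9% in wild-type and 52.8% in EPO-treated cells, and 3 of 3 of the other lists stood apart from wild-type cells, also without class B, which held 2 wild-type cells, or without C or D. This argues against globins for these lists in that contrast within the range. Globins stay open over all cells, for DNA replication and against EPO-treated cells. EPO-treated cells also had ribosomal protein and oxidative phosphorylation lists at 100 against wild-type cells in that range, the genotype as a cause stays open and untested, chip and group cannot be told apart, and separate processing of the EPO-treated columns and reads shared with ribosomal protein pseudogenes stay open for the contrast with those cells.

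Few genes were detected in suffix d cells of Flvcr-deleted class A, with a median of 343 against 1381 in suffix a. The ratio of estimated reads, suffix d over suffix a, was 0.142, and the ratio of the estimated share of reads in transcripts was 0.0814. Both fewer sequenced reads and little cellular RNA in the well are therefore consistent with the pattern, and neither excludes the other. The meaning of the suffix is not given in the sources used here. No biological explanation was tested.

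Class A of wild-type and EPO-treated cells was low in globin, and 69.2% of its 13 cells had at least 3 granulocyte and monocyte markers. A candidate explanation is cells of another type in the class, since the 9 marker cells had a median RPKM of 0 for the erythroid gene Alas2. In this class the myeloid genes Mpo and Ctsg had mean log2 levels of 5.39 and 4.68 in wild-type and 4.91 and 3.91 in EPO-treated cells. Of the 22 markers in the list, 0 are in another list and 1 was detected in at least 10% of the 96 cells of classes B to D, and the labels name Ter119 imaging but no sort that would remove such cells. An erythroid and another cell captured together is argued against for most marker cells, as 0 of 9 had Alas2 at an RPKM of at least 1 and 8 had Hbb-b1 at a log2 level of at most 4.94, against at least 12.83 in wild-type and EPO-treated cells of classes B to D. It stays open for 1 EPO-treated marker cell with Hbb-b1 at 9.53, the 1 of 9 at 1% or more of the lowest of those cells, and for an erythroid cell low in both transcripts, and early progenitors with myeloid transcripts stay open, with the biological difference untested.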

How the results depend on the processing

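The tests matched on transcript length and those in ranges of detected genes were chosen only after the result was seen. No paired analysis was possible because the cell numbers only name cells, no animal is named and no result comes from a test. Values below are percentiles among random lists unless stated otherwise, and where a value changed, the cause was not tested, except that leaving out cells leaves fewer cells.

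Of the values for lists set beside an alternative in the group contrasts and other main results, 440 had a call or none as before (52 of them without a call crossed percentile 50), 34 lost their call, 22 gained one and 13 turned, that is crossed 50 with a call before or after. For the other lists the numbers were 1001 (179 crossed), 13, 64 and 9. For single genes they were 1593 (23 that had not met the size and sign rule changed sign), 128, 36 and 10. Counts of members were close to the first count in 206 cases and moved by more than 1.5 times in 46.

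The Gata1 difference between Flvcr-deleted and wild-type cells lay between -5.62 and -2.42 over the alternatives, that of Cish between 1.28 and 4.23, and that of Hnrnpk between -7.70 and -3.73.

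Organelle clearance in EPO-treated against wild-type cells lost its call under 14 alternatives. It lay at 3.38 and 7.08 with pseudocounts of 0.1 and 10, 32.4 with no filter, 7.18 with a mean of at least 3, 6.69 with 1 sum per cell, 2.90 with that sum taken without globins and 4.26 after quantile normalization. It lay at 16.5 without the smaller chip, 3.19 with rows summed per symbol, 7.59, 22.5 and 7.27 without class B, C and D, 8.52 with the ratio of mean RPKM and 3.27 with lists matched on length.

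In Flvcr-deleted against wild-type cells, heme synthesis became apart at 0.89 with a pseudocount of 10, 0.01 with unweighted means, 2.31 without cells of few genes, 0.18 without class A, 0.14 with the ratio of mean RPKM and 0.05 in class B to D cells with 1000 to 2000 detected genes. Oxidative phosphorylation lost its call at 96.0 with a pseudocount of 0.1, 94.5 after quantile normalization, 96.1 without suffix a, 97.4 without class B, 96.5 without class C and 86.2 with lists matched on length. Globins lay at 95.9 with unweighted means, 97.3 without class A and 44.5 in the range of 1000 to 2000. GATA1-activated genes turned to 0.03 with unweighted means, 0.22 without class A and 0.00 in that range. Mitosis lay at 3.36 with 1 sum per cell, DNA replication turned to 98.98 in the range of 1000 to 2000, and EPO receptor and STAT5 targets turned to 97.9 with no filter.

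Single genes turned in that contrast. With unweighted means Hbb-b2 and Hbb-bt differed by -0.0068, Hbb-b1 by -0.032 and Hbb-bs by -0.033. In the range of 1000 to 2000 Hbb-b2 and Hbb-bt differed by -0.021, Hbb-b1 and Hbb-bs by -0.022 and Hbb-bh1 by -0.024. With the ratio of mean RPKM Hba-x differed by -0.74.

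In EPO-treated against wild-type cells with unweighted means, heme synthesis lay at 0.23, globins at 82.5 and glycolysis at 38.0, and GATA1-activated genes turned to 0.02, red cell membrane genes to 0.52 and mitosis to 0.93. In the range of 1000 to 2000 heme synthesis lay at 1.49, while globins turned to 44.6, GATA1-activated genes to 0.04, red cell membrane genes to 0.10, mitosis to 0.36, DNA replication to 99.1, glycolysis to 84.0 and the interferon response to 1.10. Glycolysis also lay at 3.49 with a pseudocount of 0.1, 2.82 without the smaller chip, 58.9 without class A and 9.57 in cells with 800 to 3000 detected genes. GATA1-activated genes lay at 97.9 without class B and 98.7 without class C. Red cell membrane genes lay at 98.7 and 98.97 under the same alternatives. Immediate early genes turned to 0.54 with no filter.

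In Flvcr-deleted against EPO-treated cells, heme synthesis became apart at 1.42 with a pseudocount of 10, 0.45 with unweighted means, 2.24 without cells of few genes, 1.92 without suffix a, 0.24 without class A and 1.32 in the range of 1000 to 2000. DNA replication lay at 6.81 with a mean of at least 3, 63.2 without class B, 2.76 without class C and 13.7 in the range of 1000 to 2000. Globins lay at 99.3 with no filter and 99.95 without class D, and GATA1-activated genes at 1.12 without class A and 98.2 without class D. Oxidative phosphorylation lay at 95.8 without suffix a and 94.3 with lists matched on length, and ribosomal proteins at 86.0 without class D. The interferon response turned to 0.82 with no filter and erythroid transcription factors to 1.61 in the range of 1000 to 2000.

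In the range of 1000 to 2000 classes hold 2 to 8 cells of a group, and calls of EPO-treated against wild-type cells were lost there with 1 class left out, such as heme synthesis at 5.78 and mitosis at 19.1 without class B.

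Other lists also gained calls. Proteasome genes did so under 4 alternatives each in Flvcr-deleted and EPO-treated against wild-type cells, yet lay at 96.7 and 95.03 in the range of 1000 to 2000. DNA replication in EPO-treated against wild-type cells gained one under 9 alternatives, mitosis and apoptosis regulators under 3 each, and organelle clearance in Flvcr-deleted against EPO-treated cells under 5. The calls that mitosis gained lay on the high side, at 99.4 without cells of few genes, 99.98 without class B and 98.04 without class C. Those to which it turned, given above, lay on the low side.

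Ribosomal proteins in EPO-treated against wild-type cells gained a call under 8 alternatives, at 100 in the range of 1000 to 2000, and in class D against class A of Flvcr-deleted cells lost theirs at 37.4 with 1 sum taken without globins.

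For class D against class A in Flvcr-deleted cells, heme synthesis became apart at 99.4 with 1 sum taken without globins, 99.8 without cells of few genes and 99.98 without suffix d. Depth limits genes at low levels: in Flvcr-deleted cells a median of 1069 genes was detected, so the absence of a transcript there is not shown by 0 detected cells.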

Other observations

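The tests with lists matched on transcript length and those in ranges of detected genes were chosen only after the result was seen. Markers of other cell types were sought in each cell, with at least 3 detected markers counted. Stem and progenitor markers were counted in 4 of 6 wild-type, 4 of 7 EPO-treated and 2 of 18 Flvcr-deleted class A cells, and in 0 cells of classes B to D. Megakaryocyte and platelet, B cell, and stromal and endothelial markers were counted in 0 cells of any group, which allows up to 7.40% of Flvcr-deleted and wild-type and 11.2% of EPO-treated cells. Macrophage markers were counted in 1 of 48 Flvcr-deleted, 1 of 48 wild-type and 1 of 31 EPO-treated cells, and T and NK cell markers in 2 of 48 wild-type cells. Mast cell, basophil and eosinophil markers were counted in 1 of 48, 3 of 48 and 1 of 31 cells.

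Detection of further genes differed between the groups. Mt1 was detected in 19 of 48 Flvcr-deleted (39.6%), 9 of 48 wild-type (18.8%) and 11 of 31 EPO-treated cells (35.5%), and Mt2 in 16, 6 and 5 cells. Nupr1 was detected in 3 of 31 EPO-treated cells (9.68%). Gata2, a progenitor factor, was detected in 8 of 48 Flvcr-deleted, 4 of 48 wild-type and 1 of 31 EPO-treated cells, and the 4 wild-type cells were of class A. Hbb-y was lower in Flvcr-deleted than in EPO-treated cells by -1.89.

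The lists not yet given against EPO-treated cells did not stand apart from random lists over all 4 classes. Flvcr-deleted cells had iron uptake and iron-sulfur assembly at 77.1, the heme and oxidative stress response at 41.3, the integrated stress response at 24.5, p53 targets at 88.4, organelle clearance at 95.4 and glycolysis at 95.1. Organelle clearance stood apart under 5 alternatives, such as 98.7 with lists matched on transcript length and 97.7 in cells with 800 to 3000 detected genes, glycolysis under 2 (97.6 with 1 sum without globins) and iron uptake under 1 (99.4 without class D). EPO-treated against wild-type cells had proteasome genes at 4.14 (1.78 after quantile normalization, 95.03 in class B to D cells with 1000 to 2000 detected genes), apoptosis regulators at 6.23 (0.60 without the smaller chip), iron uptake and iron-sulfur assembly at 21.5 and ribosome biogenesis at 60.1. In class D against class A, erythroid transcription factors lay at 55.5 in Flvcr-deleted, 100 in wild-type and 99.9 in EPO-treated cells, and DNA replication at 91.2, 87.1 and 0.01. Glycolysis lay at 20.5, 0.00 and 2.80, and oxidative phosphorylation at 87.9 (99.4 in Flvcr-deleted cells with 1 sum without globins), 0.61 (3.46 with a pseudocount of 10) and 7.12.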
